A study of Mus with 2 samples.

How the data were processed

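Gene expression was measured on Affymetrix microarrays in 2 samples of S1M, mouse gastric cancer cells that the labels assign to the ChetPS mouse model. Per the labels' protocols, cells at passage 31 were dissociated, stained with a phycoerythrin-coupled antibody against ST2 (the receptor of interleukin-33), and sorted by flow cytometry into the 15% of cells with the highest and the 15% with the lowest staining. Total RNA from each sorted fraction was converted to biotin-labelled sense cDNA and hybridised to 1 array. The labels put 1 sample in the ST2-high group and 1 in the ST2-low group, both numbered replicate 1.

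The deposited table holds log2 signals of 41345 probe sets on both arrays. The summarisation and normalization that the authors used are not given in the sources used here. The scale was read from the deposited values: they reach 13.9, above the 11.1 at which a natural-log value of a 16-bit scanner signal would end, so log2 is the scale that the range allows. The medians over all probe sets were 4.27 on the ST2-low array and 4.30 on the ST2-high array, so the arrays were on nearly the same scale as deposited. If a normalization set that scale, a global difference in RNA content between the sorted fractions would not show, and differences below are best read relative to the array's other genes. The table carries no detection calls, and the number of arrays limits the precision.

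Probe sets were named through the platform annotation table: 23521 carried 1 gene symbol, 1814 carried several and 16010 were not listed in it and are unnamed here. A gene's value was the mean over its probe sets with exactly 1 symbol, which gave 22180 genes, 1082 of them with more than 1 probe set. Of these genes, 21994 were found by gene identifier in a RefSeq table of GRCm38.p6. That table's GRCm38.p6 coordinates served, by gene, for 2 added comparisons, the genomic span of genes and which genes enclose small nucleolar RNAs. No coordinate is printed, because the build behind the array's annotation is not given in the sources used here. The transcript that encodes ST2 itself is not reported here, so the planned check of the sort against that transcript was not made.

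The comparison was the difference ST2-high minus ST2-low in log2 signal, with the values as deposited. With 1 array per group there are no residual degrees of freedom, so no test was run, no p-value is given, and no difference has a replicate check. Genes were described if their mean over the 2 arrays reached the median of all genes' means, 4.63 (the expression floor), which left 11090 genes. A difference of 2-fold (1 on the log2 scale) was the size threshold. All of these rules, the gene lists and the rule for named genes were fixed before the data were examined. The genes named are the 12 with the largest difference in each direction at or above the floor, leaving out predicted gene models, microRNAs, small nucleolar RNAs and olfactory or vomeronasal receptor genes, and up to 4 members of each gene list with the largest absolute differences. The few genes named outside that rule are marked as such.

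There were 40 gene lists, by symbol or by symbol pattern. For each list with at least 5 members above the floor (34 lists), the median difference was set against the medians of 10000 random lists of the same size, drawn from genes in the same 20 bins of mean level. A list was said to stand apart when its median ranked below percentile 2.5 or above percentile 97.5. This percentile describes these 2 arrays. It treats genes as exchangeable and is not a test across samples, and about 1.7 of 34 lists would pass by chance. In simulated arrays of 11090 genes built from these levels, 100 genes were raised and 100 lowered by a true log2 change of 1.5. Of these, 100% of the raised and 98% of the lowered genes passed the 2-fold threshold. The noise was drawn from the observed differences under 2-fold, without regard to level or to other genes. This recovery therefore follows largely from the settings. A list of 30 genes shifted by 0.25 ranked at percentile 100, and 6% of 200 unshifted lists of independently drawn genes were called. That rate does not carry over to lists of co-regulated genes.

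As a measure of noise, 1390 olfactory and vomeronasal receptor genes, which a gastric line is not known to use, had a standard deviation of 0.31 in the log2 difference at a median level of 2.70, and 7 of them passed 2-fold. Among 441 genes with 2 or more probe sets above the floor, the median standard deviation of the log2 difference between probe sets of 1 gene was 0.11. The receptor value applies mostly to levels below the floor. Both values come from the same 2 samples, so neither measures variation between repeated sorts. The alternatives were centring each array on its median, quantile and cyclic loess normalization (limma 3.58.1, R 4.3.3), the probe set with the highest level in place of the mean, 3 other floors, fold thresholds of 1.5 and 3, the mean of a list in place of its median, and 5 level bins. Matching random lists also on genomic span, and lists without genes shared with other lists, were added after seeing the data. Leaving out shared genes was run for the interferon, antigen presentation, mesenchymal and fibroblast lists only. Other steps used Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3.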

Results

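The data were 2 expression profiles of S1M mouse gastric cancer cells, 1 from the fraction with the highest surface ST2 staining (ST2-high) and 1 from the fraction with the lowest (ST2-low). The comparison asked which transcripts differ between cells of this line that carry much or little of the interleukin-33 receptor. The 2 arrays correlated with Pearson r = 0.987 over all 41345 probe sets. Among the 11090 genes at or above the expression floor, the log2 difference between the arrays had a standard deviation of 0.23 and a median of 0.03. This spread was 0.27 in the 25% of these genes with the lowest levels and 0.20 in the 25% with the highest. No group had a replicate, so every difference below compares these 2 arrays and carries no error of its own.

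At least 2-fold higher signal on the ST2-high array was found for 39 genes, and at least 2-fold lower signal for 4 genes. The largest difference was that of Angptl7, a secreted angiopoietin-like protein, at 6.33 against 4.51 (log2 difference 1.82, 3.53-fold). Its ST2-low signal is below the floor of 4.63, so that fold and its rank rest on a dim value. Fam83d, a mitotic spindle protein, followed at 7.75 against 6.10 (1.65, 3.13-fold). Spindle or cytokinesis proteins were also found further down, with Gas2l3 at 1.27 and Prc1, which bundles the central spindle, at 1.22, and the DNA helicase Pif1 was at 1.21. Mmp13, a collagenase, was higher by 1.32, Hp, the acute-phase haemoglobin scavenger haptoglobin, by 1.30, and Car2, a carbonic anhydrase, by 1.23. The genes Mcpt8, known as a basophil protease (1.23), Tnfrsf9, a costimulatory receptor (1.18), and Tigit, an inhibitory receptor of lymphocytes (1.18), were among the 12 largest as well. So was Usp18, an interferon-induced protease that removes ISG15, at 1.21. Of the 39 genes, 2 were of the classes left unnamed by rule.

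The lowest gene relative to the ST2-low array was Epcam, the epithelial cell adhesion molecule, at 4.08 on the ST2-high array against 5.82 (log2 difference -1.74, 3.35-fold). On the ST2-high array this is below the floor. Mal2 and Mal, proteolipids of apical membrane transport, were at -1.08 and -0.94. The other genes past 2-fold were Pisd-ps2 (-1.46), a pseudogene whose probes may also take signal from its parent gene, and Defb9, a beta-defensin (-1.22). On the ST2-high array both were below the floor, at 4.14 and 4.04, as were Mal at 4.39, Zfp975 at 4.34 and Kcnk1 at 4.37, so the sizes of these differences rest on dim values. Cdkn1a, the cyclin-dependent kinase inhibitor p21, was at 6.15 against 6.96 (-0.81). The remaining genes of the 12 were Zfp975 (-0.96), a member of a large zinc-finger family with similar sequences, n-R5s136 (-0.91), a copy of the repeated 5S ribosomal RNA, Rab26os (-0.90), the potassium channel gene Kcnk1 (-0.86), the pseudouridine synthase gene Pus3 (-0.78) and Pigx (-0.76), which acts in GPI-anchor synthesis.

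**Figure D1:**
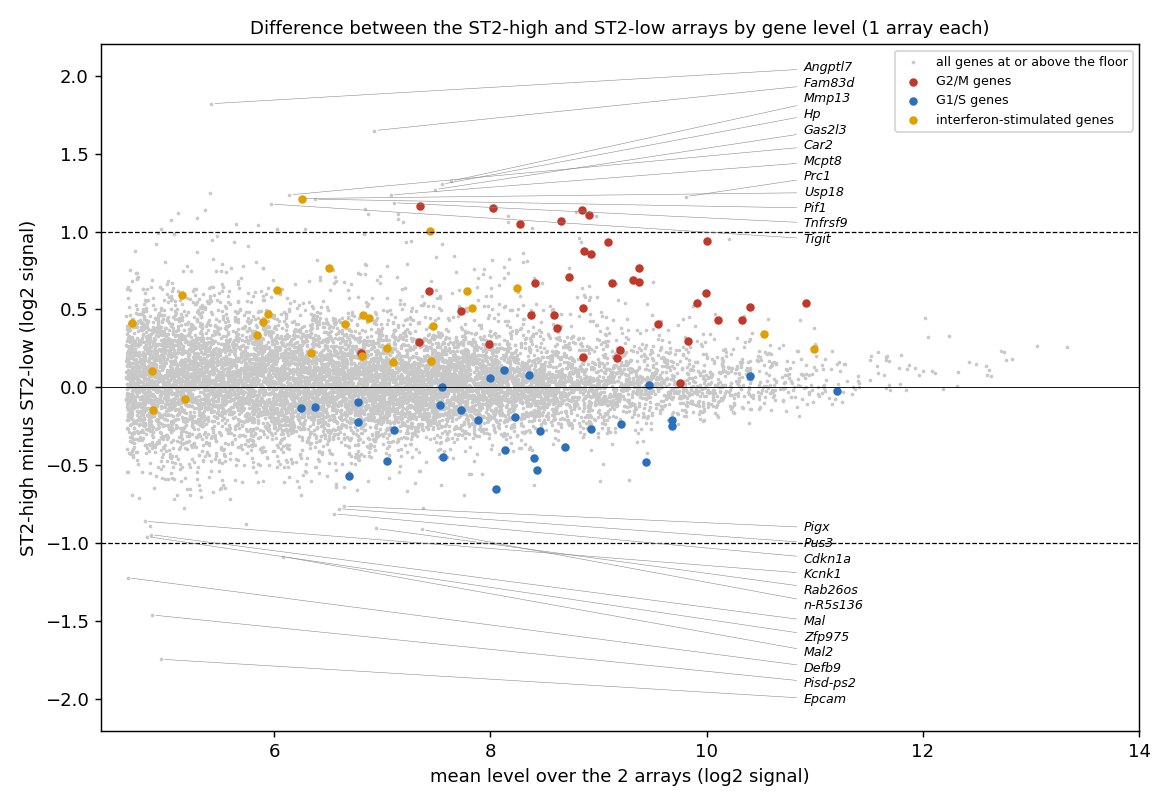
Each point is a gene at or above the floor, with its mean log2 signal over the 2 arrays on the x axis and the ST2-high minus ST2-low log2 difference on the y axis; dashed lines mark 2-fold, coloured points are members of 3 fixed lists, and the 12 genes named in each direction are labelled. The 37 G2/M genes lie above 0, 24 of the 30 G1/S genes lie below it, and 39 genes are past 2-fold upward against 4 downward.

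Genes of the G2 and M phases of the cell cycle were higher on the ST2-high array as a group, and genes of the G1/S transition were lower. All 37 measured G2/M genes had a positive difference, 6 of them past 2-fold, with a median of 0.54 (1.46-fold), above all 10000 random lists. The largest were Gtse1 (1.16), Cenpf, a centromere protein (1.15), the mitotic kinase Aurka (1.14) and Nusap1, a spindle-associated protein (1.11). Of 30 G1/S genes, 24 were lower and 5 higher, none past 2-fold, and the median was -0.22 (1.16-fold lower), below all 10000 random lists. The replication licensing gene Cdc6 was at -0.65, the chromatin assembly gene Chaf1a at -0.57, the DNA methylation cofactor Uhrf1 at -0.53 and the helicase subunit Mcm5 at -0.48. The histone list (12 genes) had a median of 0.16 at percentile 96.7 and did not stand apart.

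Interferon-stimulated genes were higher on the ST2-high array. Of 26 measured above the floor, 24 were higher, 2 of them by at least 2-fold, with a median of 0.41 (1.33-fold), above all 10000 random lists. Usp18 was at 1.21, Ifit1, an antiviral RNA-binding protein, at 1.00, the signal transducer Stat2 at 0.77 and Rtp4 at 0.64. Ifit1 was just under 2-fold after each of the 3 rescalings of the arrays, at 0.97 to 0.98. Antigen presentation genes had a median of 0.30 at percentile 99.97, with 9 of 12 higher, 2 lower and none past 2-fold. The peptide transporter gene Tap1 was at 0.60, and Ciita, the class II transactivator, was at -0.47. The class I genes H2-K1 and H2-Q4, which belong to a family of near-identical sequences, were at 0.56 and 0.49. On the ST2-low array H2-Q4 was below the floor, at 4.55. Without the floor the antigen presentation median was 0.12 at percentile 90.0 and did not stand apart.

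The list of type 2 and myeloid-recruiting cytokines was also higher, with a median of 0.25 at percentile 99.6, 7 of 10 genes higher and 3 lower. The other 9 of its 19 measured members were below the floor, among them the type 2 cytokine genes Il4, Il5 and Il13 (named outside the rule), and the call does not bear on them. Cxcl5, a neutrophil-attracting chemokine, was at 0.95, the monocyte chemoattractant Ccl2 at 0.47, Cxcl1 at 0.46 and Ccl17 at 0.37. Targets of NF-kappaB had 21 of 25 genes higher and a median of 0.13 at percentile 97.7, just past the limit. Their largest members were the same 3 chemokines Cxcl5, Ccl2 and Cxcl1, with the inhibitor gene Nfkbia at 0.43. This NF-kappaB call was lost after quantile normalization (percentile 96.8) and cyclic loess normalization (percentile 95.8). The cytokine list shares these 3 chemokines and other members with the NF-kappaB list and was not recalculated without them. Its call is therefore not separate from the NF-kappaB call. In the list of interleukin-33 receptor signalling genes, the adaptor Myd88 was at -0.22, Tab2 at -0.29, Irak2 at 0.45 and the ligand gene Il33 at 0.40. The median of the list's 13 genes above the floor was -0.06 at percentile 9.57 and the mean 0.0036, and the list did not stand apart. Il1rap, a measured member named outside the rule, was below the floor on both arrays, at 4.34 (ST2-low) and 4.50 (ST2-high).

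Mesenchymal markers were higher on the ST2-high array. Of 20 mesenchymal markers above the floor, 17 were higher, with a median of 0.21 at percentile 99.96. The stromelysin gene Mmp3 was at 1.12, the collagen crosslinking enzyme Lox at 0.65, and Tgfbi and Col1a1 were both at 0.31. The fibroblast list, which shares genes with the mesenchymal list, had a median of 0.20 at percentile 98.6, with Dcn, a matrix proteoglycan, at 0.42 and Col6a2 at 0.27. It did not stand apart without the genes that other such lists hold (5 genes, median 0.15, percentile 88.9), with no floor (0.14, percentile 96.0), with the floor at the 75th percentile of levels (0.07, percentile 72.6) or by the mean (0.18, percentile 96.4). Targets of the coactivator YAP had 20 of 23 genes higher and a median of 0.24, above all 10000 random lists, with Nt5e at 0.46, the matricellular gene Ccn1 at 0.43 and Rbms3 at 0.33, while Fjx1 was at -0.57. Hypoxia and glycolysis genes had 20 of 25 higher and a median of 0.17 at percentile 99.9. These included Adm, which encodes the vasodilator adrenomedullin (1.11), Pfkfb3, a regulator of glycolysis (0.66), and the hydroxylase genes Egln3 (0.38) and P4ha1 (0.37). The 5 lower genes included Egln1 (-0.21) and Vegfa (-0.20), both named outside the rule. The TGF-beta target list did not stand apart (median 0.09, percentile 88.0).

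Epithelial markers as a list did not stand apart at the chosen floor, with 5 of 12 genes higher, 7 lower and a median of -0.04 at percentile 7.64. Its members went both ways. Besides Epcam, the protease inhibitor gene Spint1 was at -0.54 and the keratin Krt19 at -0.51, whereas the claudin Cldn3 was at 0.24. With no floor, all 24 measured members had a median of -0.13 at percentile 0.04, and with the floor at the 75th percentile of levels the remaining members had a median of 0.20 at percentile 97.7. At the chosen floor the mean of the members was -0.19 at percentile 0.03, so the call depended on the summary as well as on the floor. Stem-cell and tumour-initiating markers had 8 of 19 genes higher and 11 lower, with a median of -0.03 at percentile 10.6. Cd24a, a surface glycoprotein, was at -0.55, the transcription factor Sox2 at -0.42, the integrin Itga6 at -0.28 and the Wnt target Axin2 at 0.47. On the ST2-low array Axin2 was below the floor, at 4.51, so the size of its difference rests on a dim value. That list stood apart as lower with no floor (median -0.09, percentile 0.26). Of 25 gastric lineage markers, 9 were above the floor, 4 of them higher and 5 lower (median -0.05, percentile 12.6). Sox2 (-0.42) is also in this list and had its largest difference. The trefoil factor genes Tff2 and Tff1 were at 0.31 and 0.16, and Gata4 was at -0.15. Of 20 intestinal markers, only Cdx2 (-0.41) and Tff3 (0.11) were above the floor.

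Apoptosis and drug-handling genes did not stand apart. The 11 anti-apoptotic genes had a median of 0.03 at percentile 51.4, with Bcl2 at 0.18 and Birc5, which is also in the G2/M list, at 0.49. The 16 pro-apoptotic genes had a median of -0.06 at percentile 4.58, with Bad at -0.38, Bcl2l11 at -0.33 and Casp9 at 0.33. Efflux and detoxification genes had 13 of 18 higher and a median of 0.09 at percentile 84.5, with the similar transporter genes Abcb1a and Abcb1b at 0.42 and 0.28. The p53 target list had a median of 0.09 at percentile 83.2, with Polk at 0.56 and Cdkn1a, as above, at -0.81. Targets of the MAPK pathway had a median of -0.06 at percentile 1.22, which placed them lower, with the phosphatase genes Dusp6 at -0.44 and Dusp4 at -0.36 but Dusp1 at 0.44. Their mean was -0.0031 at percentile 13.0, so this call held for the median and not for the mean.

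Ribosomal protein genes were slightly lower on the ST2-high array, with 45 of 58 lower and a median of -0.07, below all 10000 random lists. Rps26 was at -0.50, Rpl17 at -0.46, Rpl37 at -0.44 and Rps16 at 0.45, and genes of this family have many processed copies that can share probes. The proteasome list had 25 of 35 genes lower and a median of -0.05 at percentile 0.155. It was matched by symbol, and not all of its members encode subunits (Psmc3ip, at -0.21, does not). The lists of complex I (median -0.0046, percentile 15.1, mean 0.0084), cholesterol synthesis (0.07, percentile 82.5), unfolded protein and amino-acid stress response (0.03, percentile 46.8), Wnt targets (0.08, percentile 67.6) and Notch genes (0.03, percentile 43.9) did not stand apart. Neither did immediate-early and dissociation stress genes (0.02, percentile 47.2) or the reference genes (0.11, percentile 93.4). In all, 15 of 34 lists stood apart, 10 higher and 5 lower, and 10 of these 15 kept the call in every alternative run on them.

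Most markers of immune and endothelial cells were below the floor on these arrays, whereas 8 of 15 fibroblast markers were above it, 7 of them higher on the ST2-high array, Col3a1 among them at a mean level of 9.57 (0.24). Of 49 measured markers of mast cells, basophils, lymphocytes, macrophages and neutrophils, 4 were above it, namely Mcpt8 (1.23), Gata2 (0.08), Cd14 (0.49) and Cd68 (0.48). Of 15 endothelial markers, 3 were above the floor, with Plvap at 0.23, Flt1 at -0.17 and Egfl7 at 0.01. No mitochondrially encoded gene was found among the genes with a symbol here, so these transcripts were not assessed.

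**Figure D2:**
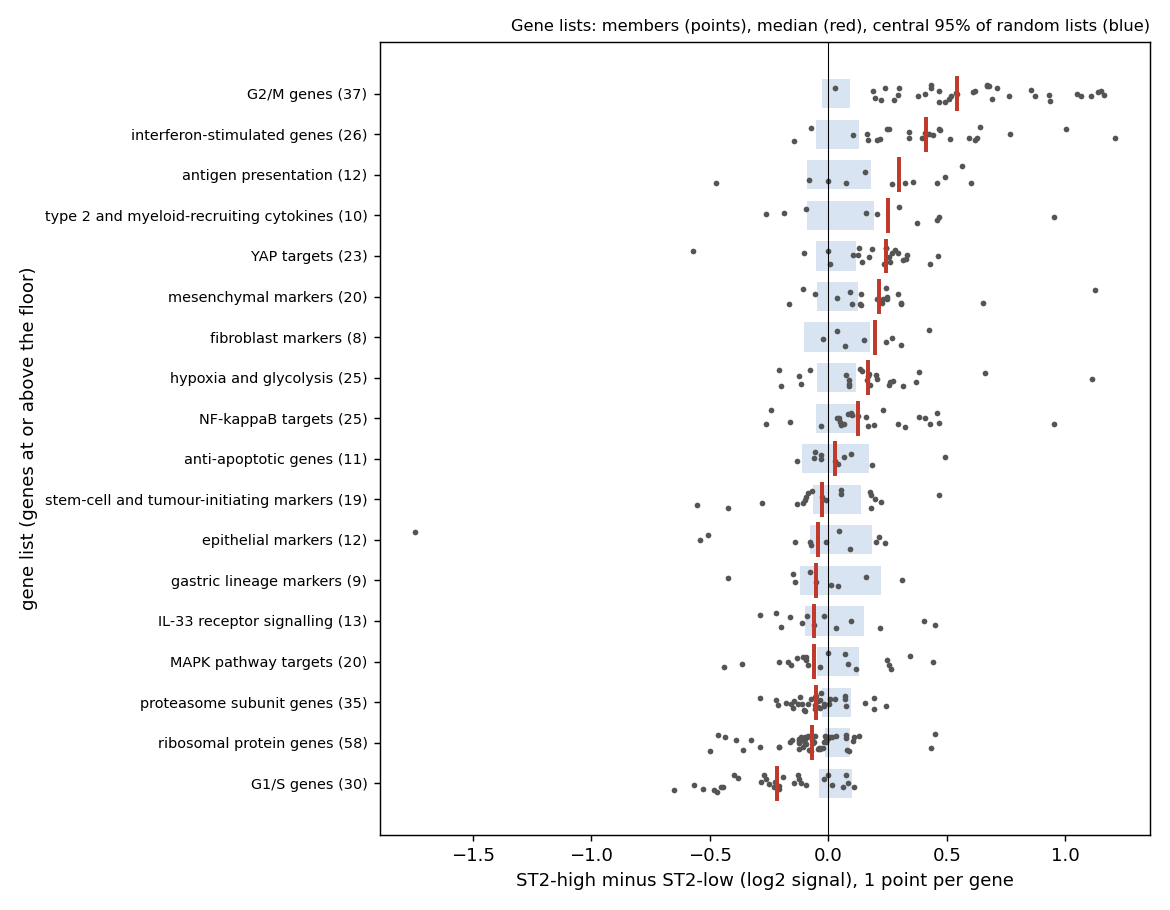
Each point is a gene of a fixed list at or above the floor, placed on the x axis by its ST2-high minus ST2-low log2 difference; the red line is the list's median, the blue band spans the central 95% of the medians of 10000 level-matched random lists, and the number of genes is in parentheses. The median of the G2/M list (0.54) and that of the interferon list (0.41) lie to the right of their bands, and that of the G1/S list (-0.22) lies to the left.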

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

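No replicate could be left out and no paired analysis was possible because each group held 1 array. Counts of genes past 2-fold were 34 or 35 higher and 4 or 5 lower under the 3 rescalings, all but 1 of them among the original 39 and 4. With the probe set with the highest level they were 39 and 3, and 12 of the 12 highest and 11 of the 12 lowest named genes were shared. The counts followed the floor and threshold by construction. They were 66 higher and 23 lower with no floor, and 24 and 0 with the floor at the 75th percentile. With the floor at the receptor genes' 95th percentile they were 43 and 7. At 1.5-fold they were 202 and 59, and at 3-fold 2 and 1. Of the 339 recalculated list medians, 320 kept their side of the percentile limits, and the cause of the other 19 was not tested. No list that stood apart reversed, and lists that did not stand apart could not be counted as reversed. The epithelial list, one of the latter, was called lower in some alternatives and higher in another, as given below. The 34 medians from centring are among the 320 by construction, since centring shifts all genes alike and leaves each percentile as it was. The NF-kappaB call was lost with quantile normalization (0.086), cyclic loess (0.082), the probe set with the highest level (0.13) and the 75th percentile floor (0.13). With no floor, calls were lost for antigen presentation (0.12), fibroblast markers (0.14) and microRNA genes (0.00), and gained as lower for stem-cell markers (-0.085) and epithelial markers (-0.13). With the 75th percentile floor, calls were lost for fibroblast markers (0.071) and microRNA genes (0.091), and gained for stem-cell markers (lower, -0.087), epithelial markers (higher, 0.20) and histone genes (higher, 0.21). Epithelial markers also became lower with the receptor floor (-0.077) and with the mean (-0.19). The mean lost the calls for MAPK targets (-0.0031) and fibroblast markers (0.18), and leaving out shared genes lost that for fibroblast markers (0.15). Of 556 recalculated differences of named genes, 552 kept their side of 2-fold. The exceptions were Ifit1 (0.97 in 2 rescalings and 0.98 in the other) and Zfp975 (-1.01 after cyclic loess). Without detection calls, signal over background is judged from the floor alone, and the spread of differences is widest among the dimmest genes (0.27 against 0.20 in the brightest).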

Other observations

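Small nucleolar RNAs, which guide the modification of ribosomal RNA, were lower on the ST2-high array. Of 64 above the floor, 54 were lower and 10 higher, with a median of -0.22, below all 10000 random lists. The measured genes that enclose them had a median of -0.09 over 35 genes, also below all random lists, and of -0.04 at percentile 1.64 over the 25 that are not ribosomal protein genes. Of these 25, 16 were lower and 9 higher. The lowest were Snhg12 at -0.64, Snhg3 at -0.47 and Snhg1 at -0.35. Zbed3 was at 0.13, Ap1g1 at 0.12 and Kansl2 at 0.11, so the host genes did not all follow the small nucleolar RNAs. Rnu3a, which encodes the small nucleolar RNA U3 and is not in the list, was at -0.69. Other short structured RNAs had a median of -0.08 at percentile 1.72, with 9 of 12 lower, among them Scarna6 at -0.40, while Rn7sk was at 0.18. MicroRNA genes above the floor went the other way, with 67 of 97 higher and a median of 0.10 at percentile 98.5, a call that did not hold without the floor. The groups of host genes and short structured RNAs, and the genes named from them, were chosen after the small nucleolar RNA values had been seen.

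Among the 5249 unnamed probe sets above the floor, 81 were at least 2-fold higher and 90 at least 2-fold lower. The counts for the 11090 genes above the floor were 39 and 4. Unnamed probe sets thus passed 2-fold more often, and about equally in both directions, for reasons that were not tested. The 50 olfactory and vomeronasal receptor genes above the floor had a median of 0.05 at percentile 40.0, and the 527 predicted gene models one of 0.03 at percentile 10.2.

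The value for cell size and the test on dim probe sets were chosen after the results they bear on had been seen, and the other tests below were set before their own results were known.

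The first pattern is the higher G2/M and lower G1/S signal in ST2-high cells. Random lists matched on level argue against a trend of the difference with signal level. The Spearman correlation of difference and level over genes above the floor was also only -0.04. The G2/M median of 0.51 after cyclic loess normalization was still above all random lists. It adds little, because the matching on level already covered such a trend. A trend with gene length is argued against by percentile 100 for the G2/M list among random lists matched on level and genomic span, although genomic span is not transcript length. A candidate explanation is that a gate on total fluorescence takes larger, later-cycle cells. The gap of 0.76 between the G2/M and G1/S medians restates the pattern and does not test this, and a link between cycle phase and ST2 would give the same gap, so the 2 cannot be told apart without scatter or DNA content.

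The second pattern is the higher interferon-stimulated signal. RNA from immune cells in the ST2-high sort is argued against by a median level of 3.74 for 8 abundant leukocyte transcripts on that array, below the floor of 4.63, with only Coro1a, named outside the rule, above it at 4.88. Between the arrays these 8 transcripts, named outside the rule, went both ways at dim levels. Lyz2 was at -0.67, Cd3e at -0.59, Laptm5 at -0.30, Ptprc at -0.14 and Fcer1g at -0.09. Tyrobp was at 0.04, Coro1a at 0.11 and Cd52 at 0.29. Single immune genes were nevertheless above the floor and higher on the ST2-high array. These were Mcpt8 (1.23), Tigit (1.18), Tnfrsf9 (1.18), Cd14 (0.49) and Cd68 (0.48), and their source was not tested. The interferon list also stayed at percentile 100 when matched on genomic span. A difference in interferon signalling between ST2-high and ST2-low cells may account for the list and remains untested.

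The third pattern is the lower signal of Epcam and several other epithelial genes. Below the floor, 10 of 12 members of the fixed list were lower, among them Cldn4 (-1.38), St14 (-1.003) and Cldn7 (-0.81), which were named after their values were seen. A second list of 27 epithelial genes that shares none with the first had a median of -0.043 at percentile 3.16 over all its measured members, only 11 of them above the floor, with 14 lower and 13 higher. That median lies inside the central 95% of random lists, so noise of dim probe sets is not excluded and whether a wider set of epithelial genes is lower stays open. A small share of Epcam-positive cells in the ST2-low fraction could give such a pattern, and so could a graded change in all cells, and 2 bulk arrays do not separate them.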
